A study of Mus musculus with 3 samples.

How the data were processed

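Gonads of male mouse embryos lacking Cyp26b1 were profiled at 3 embryonic stages (E12.5, E13.5 and E14.5) on 1-colour Agilent expression arrays. Per the labels, the gonads were kept in RNAlater, RNA was purified on RNeasy columns, and Cy3-labelled cRNA was made from 0.20 µg RNA by linear amplification. Each of the 3 samples holds 2 arrays, which the series describes as biological duplicates, so 6 arrays were analysed. Arrays of a control genotype are not among these samples and were not analysed here.

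Per the file headers, the scanner files hold the spot intensity from Agilent Feature Extraction 9.5, background-subtracted and spatially detrended but not scaled between arrays. They also hold the median intensity of each spot and of its local background, and flags for outlier, saturated and well-above-background spots. The deposited table of the authors holds 1 linear ratio per probe and stage against a reference that is not stated. It was checked against the scanner files. For the 25605 probes well above background on all arrays, log2 differences between its columns had a correlation across probes of 1.0 with those of the scanner values, and 99.99% lay within 0.05 of a constant offset. Over all 41153 probes the correlation was 0.892, 0.935 and 0.950 for the 3 pairs of stages, and how dim probes were treated is not stated. Probes are not independent replicates.

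Signals were log2-transformed, each array's 75th percentile was subtracted, outlier spots were left out, and repeated spots were averaged. Of 41174 probes, 21 missing on an array were left out. Gene symbols came from RefSeq accessions, which named 23545 probes of 16620 genes, while 17608 probes had no symbol. Genome positions were not used here. For the 5511 genes with several probes, the brightest probe stood for the gene. A gene was kept when well above background on both arrays of at least 1 stage, which left 13484 genes. For a gene above background on no array of the dimmer stage, a change is given only as a bound, computed against the lowest signal called above background on each array of that stage. With such genes at their bound, list medians were the same except for the neural list between E13.5 and E14.5, at 0.01 in place of 0.07.

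Stages were compared with limma 3.58.1 in R 4.3.3 on all 6 arrays (lmFit and eBayes without a trend, 3 residual and 2.96 prior degrees of freedom). The threshold was a Benjamini-Hochberg adjusted p of 0.05 with no fold minimum. All limma tests were two-sided. Gene lists were tested with camera at a preset correlation of 0.01 over the 22 lists with at least 5 genes measured, of 23 fixed. Camera with an estimated correlation and fry were run beside it. The comparisons, the lists and the rule for named genes were chosen before the data were examined. That rule takes the 10 largest rises and the 10 largest falls past the threshold without overlap between the 2 stages, up to 4 members of each list, and 14 genes fixed by name. A member named to spell out a count of 5 or fewer, where the rule did not select it, was named after its values were seen. Insl3, 1 of the 14, was matched to no probe that passed these steps.

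Data were simulated with the spread of these arrays and with 200 of 13484 genes changed in each comparison. There, 2-fold changes were recovered in 56%, 54% and 50% of genes for E13.5 against E12.5, E14.5 against E13.5 and E14.5 against E12.5. Recovery depends on how many genes change. These shares therefore do not carry over to the measured comparisons, which called 4318, 7 and 6299 genes. For 4-fold changes the shares were 92%, 90% and 96%. False calls numbered 7 of 131, 5 of 126 and 2 of 126. The spread was drawn from the prior that limma fitted, with no slide difference put in, so a low false share was built in. It does not carry over to the measured comparisons with E12.5, whose arrays lay on another slide than the later ones. No list passed when none was moved, and the moved list passed in each comparison. The genes were simulated independently, so this does not test camera on lists whose genes are correlated. In the measured lists the estimated correlation ran from -0.05 (oogenesis) to 0.825 (pluripotency).

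Alternatives were normexp background correction (offset 50), quantile and median scaling, other background filters, the mean of all probes, other variance priors, a replicate block, a slide block, 4 arrays only, a 2-fold minimum and leaving out each array. Normexp used the spot medians because the files hold no spot means. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 in Python 3.11.15. The number of arrays limits the precision of every value.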

Results

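Gene expression was measured in male gonads of Cyp26b1 knockout mouse embryos of the MCH line, with 2 arrays at each of E12.5, E13.5 and E14.5. Cyp26b1 encodes a cytochrome P450 that breaks down retinoic acid. The comparisons ask how expression in the knockout gonad moved from stage to stage. On the 6 arrays, 65.3% to 70.1% of probes were well above background, and 0 spots were saturated. Genes well above background on both arrays numbered 12843 at E12.5, 13166 at E13.5 and 13084 at E14.5, and 12544 genes were so at all 3 stages. Both arrays of E14.5 and no array of E12.5 showed 274 genes, and 131 genes were in the opposite case. Across genes, the duplicate arrays had Pearson r of 0.993 at E12.5, 0.996 at E13.5 and 0.994 at E14.5, where genes are not independent replicates. The SD of the log2 difference between duplicates was 0.363, 0.295 and 0.332. An E13.5 and an E14.5 array, the second and the first of their pairs, were as close as duplicates, with an SD of 0.339.

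Both E12.5 arrays lay on 1 slide and the 4 later arrays on another. A difference between E12.5 and a later stage can therefore not be told apart from a difference between slides by these fits, and only E14.5 against E13.5 lies within a slide. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were well above background on all 6 arrays, and Xist on 0. The single Cyp26b1 probe was well above background on all 6 arrays, at log2 signals over the 75th percentile of 4.96 and 4.73 at E12.5, 4.29 and 4.2 at E13.5, and 4.27 and 3.83 at E14.5. Its position relative to the deleted part of the gene is not known here, so the signal does not test the deletion. The change from E12.5 was -0.60 ± 0.17 at E13.5 (adjusted p = 0.045) and -0.80 ± 0.17 at E14.5 (adjusted p = 0.0135). The first call was lost without any 1 of the 4 arrays compared (adjusted p 0.077 to 0.177), with normexp (-0.42, 0.0628), with no background filter (0.0836) and with unnamed probes (0.0627). The second was lost without the first E12.5 array (0.0645) or the second E14.5 array (0.0502). Changes below are log2 differences of stage means ± SE from limma, with n = 2 arrays per stage.

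Between E12.5 and E14.5, genes of meiosis rose together. Stra8, which responds to retinoic acid and is needed to enter meiosis, rose 7.75-fold (2.95 ± 0.17, adjusted p = 0.000505). Sycp3, of the synaptonemal complex, rose 9.42-fold (3.24 ± 0.22), the meiotic cohesin gene Rec8 rose 5.72-fold (2.52 ± 0.20), and the recombinase gene Dmc1 rose 5.15-fold (2.36 ± 0.17). Terb1, which ties meiotic telomeres to the nuclear envelope, rose at least 20.0-fold. Of 40 meiosis genes 23 were measured, of which 19 rose, 1 fell (Trip13, -0.44 ± 0.14) and 3 did not pass, with 19 and 1 when adjusted over the list alone. The list median was 1.97, with a camera adjusted p = 5.48e-07 and an adjusted p = 0.418 with an estimated correlation.

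**Figure D1:**
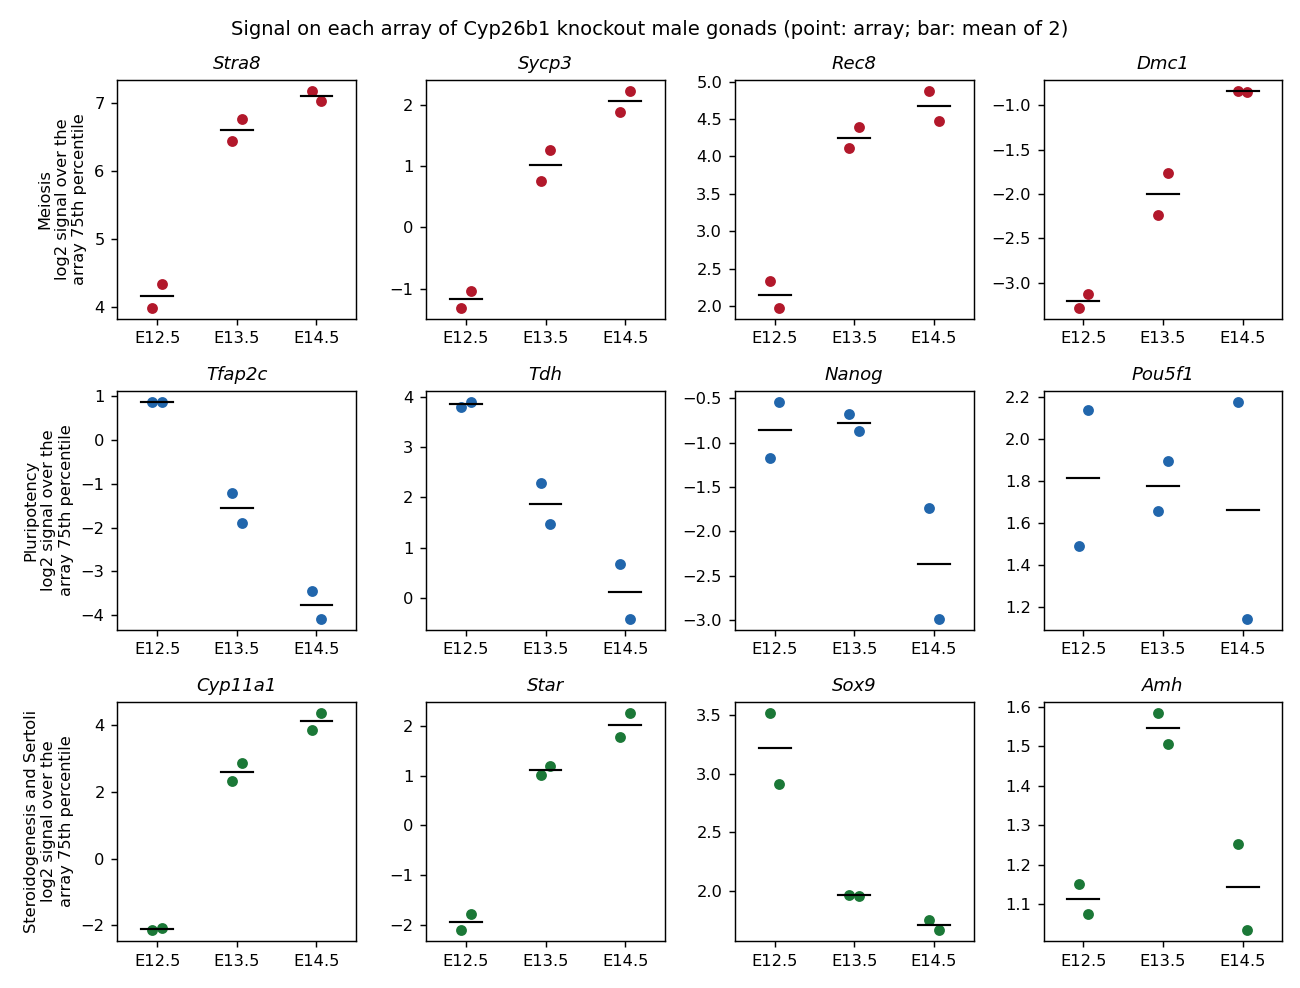
Log2 signal over the 75th percentile of each array for 12 genes at E12.5, E13.5 and E14.5, with points for arrays and bars for the mean of 2. Stra8, Sycp3, Rec8 and Dmc1 were higher on both E14.5 arrays than on both E12.5 arrays, Tfap2c and Tdh were lower, and the Pou5f1 arrays overlapped.

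Other germ cell genes rose as well between E12.5 and E14.5. Nanos2, a regulator of male germ cell fate, rose at least 7.15-fold, Mov10l1 of the piRNA pathway rose by 2.77 ± 0.25 on its brightest probe, with its other probe at 1.23, and the germ cell helicase gene Ddx4 rose by 1.05 ± 0.11. Dnmt3a, of the male germ cell list, was at 1.18 on its brightest probe but at -0.58 and -0.45 on its other probes. Dnmt3l rose by 1.61 ± 0.32 (adjusted p = 0.0105, and 0.0561 without the first E12.5 array). Dazl, an RNA-binding protein of germ cells, rose by 0.84 ± 0.19 on its brightest probe and was at -0.29 on its other probe. The Dazl call was lost with the mean of both probes (adjusted p = 0.25), without the first E12.5 array (0.0507) and without the first E14.5 array (0.0643). Of 16 male germ cell genes 9 rose, 3 fell (Dnd1, Lefty2 and Tdgf1) and 4 did not pass, the same when adjusted over the list alone (median 0.95, camera adjusted p = 0.047, adjusted p = 0.418 with an estimated correlation). Of 15 genes of the general germ cell list 9 rose, 2 fell (Dnd1 and Kit) and 4 did not pass, again the same when adjusted over the list alone (median 0.96, camera adjusted p = 0.0227, adjusted p = 0.418 with an estimated correlation). These 2 list calls were lost without the first E12.5 array (adjusted p 0.106 and 0.0707), and the male list call also with normexp (0.063), quantile normalization (0.0573) and the mean of probes (0.0625).

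Falls led among pluripotency genes between E12.5 and E14.5. Tfap2c, a transcription factor of early germ cells, was 25.1-fold lower (-4.65 ± 0.28, adjusted p = 0.000543), and Tdh, the threonine dehydrogenase gene of mouse pluripotent cells, was 13.2-fold lower (-3.72 ± 0.41). Tdgf1 fell by 3.42 ± 0.31, and Tcl1 fell by 2.41 ± 0.51, a call lost without the second E12.5 array (adjusted p = 0.0667). Tcl1 was at -3.17 and -1.67 without the first or second E14.5 array. Pou5f1 was at -0.15 ± 0.37 and did not pass (adjusted p = 0.757). Of 21 genes measured 13 fell, 1 rose (Klf2) and 7 did not pass, the same when adjusted over the list alone. The list median was -1.03 (camera adjusted p = 0.000153, adjusted p = 0.497 with an estimated correlation), and -0.68 without the second E14.5 array. Cell cycle genes also fell, among them the mitotic kinesin gene Kif11 (-1.45 ± 0.10), the kinase gene Cdk1 (-1.08 ± 0.15) and Ttk (-1.30 ± 0.18). Of 31 measured 19 fell, 1 rose (Bub1) and 11 did not pass, with 21 and 1 when adjusted over the list alone (median -0.50, camera adjusted p = 8.6e-05, adjusted p = 0.418 with an estimated correlation).

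In the somatic lists, fetal Leydig genes rose most between E12.5 and E14.5. Cyp11a1, which starts steroid synthesis from cholesterol, rose 75.1-fold (6.23 ± 0.24, adjusted p = 0.000221). Cyp17a1, needed for androgen synthesis, rose 35.7-fold (5.16 ± 0.29), and Star, which carries cholesterol into mitochondria, rose 15.5-fold (3.95 ± 0.20). Of 18 genes measured 16 rose, 0 fell and 2 did not pass in limma, with 17 and 0 when adjusted over the list alone (median 1.99, camera adjusted p = 1.13e-07, adjusted p = 0.418 with an estimated correlation). Sertoli genes moved both ways, 9 higher, 6 lower and 12 not past of 27, with 10 and 6 when adjusted over the list alone (camera adjusted p = 0.409). Sox9, which directs Sertoli cell fate, fell by 1.5 ± 0.20 on its brightest probe, with its other probes at -1.24 and -0.70. Fgf9 fell by 2.15 ± 0.15, and Defb36 rose by 3.51 ± 0.28. Amh, the hormone that removes the Müllerian ducts, was at 0.03 ± 0.12 and did not pass (adjusted p = 0.845).

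Retinoic acid genes rose between E12.5 and E14.5, among them Lrat, which stores retinol as esters (2.36 ± 0.25), and Rbp4, the retinol carrier of blood (1.69 ± 0.19). Of 24 measured 15 rose, 3 fell (Cyp26b1, Fabp5 and Rara) and 6 did not pass, with 17 and 3 when adjusted over the list alone (median 0.54, camera adjusted p = 0.00396, adjusted p = 0.418 with an estimated correlation). Stra8 belongs to this list and to the meiosis list. Among macrophage genes the rises included Lyz2 at 1.33 ± 0.18 and Csf1r at 1.02 ± 0.16. Of 19 measured 8 rose, 0 fell and 11 did not pass in limma, the same when adjusted over the list alone (median 0.50, camera adjusted p = 0.0128, adjusted p = 0.418 with an estimated correlation). Of 7 oogenesis genes measured 5 rose, 1 fell (Padi6) and 1 did not pass, with 5 and 1 when adjusted over the list alone. Figla, a transcription factor of oocytes, rose at least 36.9-fold. The Padi6 fall was lost with normexp (-0.02, adjusted p = 0.923) and without the second E12.5 array (0.0516). The oogenesis list as a whole did not pass (camera adjusted p = 0.0619). It passed with normexp (0.019), median scaling (0.0183), the filter on all 6 arrays (0.0337) and without the first E14.5 array (0.0223).

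Falls led among erythroid and mesonephric genes between E12.5 and E14.5. The embryonic globin genes Hbb-bh1 (-4.15 ± 0.45), Hbb-y (-2.86 ± 0.47) and Hba-x (-2.10 ± 0.33) fell, as did the erythroid factor Klf1 (-2.70 ± 0.34). Without the first or second E14.5 array Hbb-bh1 was at -4.87 and -3.43, Hbb-y at -3.59 and -2.13, and Hba-x at -2.56 and -1.65. Of 15 erythroid genes 9 fell, 1 rose (Hba-a1) and 5 did not pass, the same when adjusted over the list alone (median -1.14, camera adjusted p = 0.00814, adjusted p = 0.418 with an estimated correlation). Lhx1, a transcription factor of the developing kidney (-2.70 ± 0.31), and Calb1 (-2.10 ± 0.20) led the 12 of 17 mesonephros and duct genes that fell, with 1 rise (Pax2) and 4 not past, the same when adjusted over the list alone. That list had a median of -0.70 (camera adjusted p = 0.00127, adjusted p = 0.418 with an estimated correlation), and of -0.45 without the second E14.5 array. In the hypoxia and glycolysis list 7 of 17 fell, 0 rose and 10 did not pass in limma, the same when adjusted over the list alone (median -0.29, camera adjusted p = 0.0227, adjusted p = 0.497 with an estimated correlation). Without the second E14.5 array the hypoxia median was -0.02 (adjusted p = 0.127), without the first it was -0.56, and the call was lost with the mean of probes (0.0508). In the pregranulosa list 6 of 17 fell, 2 passed upward (Wnt4 and Irx5) and 9 did not pass, the same when adjusted over the list alone (median -0.31, camera adjusted p = 0.047, adjusted p = 0.418 with an estimated correlation). No rise is read for Irx5, which was well above background on 0 arrays of either stage and was lost with a trend and robust prior (0.0585) and without the second E14.5 array (0.0525). The pregranulosa call was lost with normexp (median -0.15, 0.172), median scaling (0.0686) and unnamed probes (0.0513), without the first E12.5 array (0.0907) and without the second E14.5 array (0.275), and the median was -0.49 without the first E14.5 array.

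In the lists that did not pass between E12.5 and E14.5, single members still changed. Cnn1 (3.19 ± 0.24), Inhba (2.54 ± 0.22) and Tagln (2.20 ± 0.23) were among 8 rises, 2 falls and 11 not past of 21 peritubular and interstitial genes (camera adjusted p = 0.523). The median of that list was -0.03 while its mean, 0.50, and its test pointed up, and the sign of the median changed with the scaling, as it did for the neural list. Extracellular matrix genes gave 11 rises, 1 fall (Fbln2) and 13 not past of 25 (0.124, 0.0218 without the first E14.5 array and 0.0472 with the mean of probes), led by Bgn (2.01 ± 0.31). Endothelial genes gave 2 rises, 8 falls and 11 not past of 21 (0.0998), with Kdr, a receptor for vascular growth factor, at -0.86 ± 0.13. Apoptosis genes gave 3 rises, 8 falls and 13 not past of 24 (0.0541, 0.0277 without the second E12.5 array, 0.0218 without the first E14.5 array and 0.0326 with the mean of probes), with Pmaip1 at -2.36 ± 0.21. Immediate early and stress genes gave 8, 5 and 5 of 18 in the same order (0.59), with Hspa1a at 2.95 ± 0.22 and Myc at -1.26 ± 0.13. Cell cycle arrest genes gave 3, 6 and 8 of 17 (0.684), with Cdkn2a at 3.61 ± 0.22. Coelomic surface genes gave 2, 2 and 5 of 9 (0.934), with Msln at 3.1 ± 0.33, and neural genes gave 2, 1 and 8 of 11 (0.739), with Elavl3 at 2.28 ± 0.32. When adjusted over the list alone, rises and falls were 8 and 2 for peritubular, 11 and 2 for matrix, 2 and 8 for endothelial, 3 and 8 for apoptosis, 8 and 6 for stress, 3 and 7 for arrest, 2 and 2 for coelomic and 2 and 1 for neural genes.

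Over all genes, 6299 of 13484 changed between E12.5 and E14.5, 3445 higher and 2854 lower (54.7% higher), and 1924 of them by at least 2-fold. Beside Cyp11a1 and Figla, the named rises were Hao2 (59.2-fold), Rhox3a (57.3-fold), Taf7l (49.2-fold), Jak3 (43.4-fold on its brightest probe, with 1 of its 3 probes at -0.63), Lypd4 (at least 53.2-fold), Sftpc (at least 36.7-fold) and Fam205c (at least 16.2-fold). Bcan rose, with no fold given, since it ran from 3.88 to 7.18 without the second or first E12.5 array and its call was lost without the second E14.5 array (adjusted p = 0.0539). Beside Tfap2c and Hbb-bh1, the named falls were Pnliprp2 (-4.79 and -3.34 without the first or second E14.5 array), Umodl1 (at least 15.9-fold), Khdc1c (at least 13.1-fold), Pla2g4e (at least 7.48-fold), Sprr2d (at least 6.35-fold) and Kcnc1 (at least 4.88-fold, and at least 2.61-fold without the second E12.5 array). The Kcnc1 fall rests on its brightest probe alone. Its other probes, well above background on 0 arrays, were at -0.50 and -0.52. No fall is read for Slc4a7, at -5.02 on its brightest probe but at -0.38 and -0.01 on its other probes, all well above background on 6 arrays, with a call lost without single arrays (adjusted p 0.0565 to 0.0704). Slc9c1 is given without a fold because its call was lost with normexp (-0.98, 0.133), with no filter (0.0636) and without single arrays (0.0501 to 0.0966). With median scaling 5753 genes changed and 41.1% of them were higher, and the median change of all genes was -0.12 in place of 0.03. Without the second E14.5 array 3937 genes changed.

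Between E12.5 and E13.5, rises led among meiosis and Leydig genes and falls among mesonephric and erythroid genes, lists that did not pass with an estimated correlation (adjusted p = 0.457). Stra8 rose 5.47-fold (2.45 ± 0.17, adjusted p = 0.00181), Sycp3 4.57-fold (2.19 ± 0.22), Rec8 4.27-fold (2.09 ± 0.20) and Dmc1 2.31-fold (1.21 ± 0.17). Cyp11a1 rose 26.3-fold (4.72 ± 0.24), Cyp17a1 17.4-fold (4.12 ± 0.29) and Star 8.21-fold (3.04 ± 0.20). Calb1, a mesonephric duct gene, fell by 2.24 ± 0.20. Nanos2 rose at least 6.30-fold, Terb1 at least 8.87-fold and Ddx4 2.02-fold (1.01 ± 0.11), and Sox9 fell by 1.25 ± 0.20, with its other probes at -0.83 and -0.44. Dazl rose by 0.93 ± 0.19, with its other probe at -0.04, a call lost with the mean of both probes (0.106) and without the first E12.5 array (0.0572), the first E13.5 array (0.0608) or the second (0.0833). Amh rose by 0.43 ± 0.12 (adjusted p = 0.0386), a call lost without any 1 of the 4 arrays compared, where it ran from 0.39 to 0.47. The Amh call was also lost with median scaling (0.38, adjusted p = 0.121), with no background filter (0.0703) and with unnamed probes (0.057). Dnmt3l (0.74 ± 0.32) and Pou5f1 (-0.04 ± 0.37) did not pass.

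By list, 17 of 23 meiosis genes rose between E12.5 and E13.5, 0 fell and 6 did not pass in limma, with 19 and 0 when adjusted over the list alone (median 1.49, camera adjusted p = 2.91e-07). Of 18 fetal Leydig genes 14 rose, 1 fell (Mc2r) and 3 did not pass, with 16 and 1 when adjusted over the list alone (median 1.24, 5.34e-07). Male germ cell genes gave 8 rises, 1 fall (Tdgf1) and 7 not past of 16 (median 0.83, 0.0125), and the general germ cell list gave 9, 1 (Kit) and 5 of 15 (median 0.90, 0.00477), both the same when adjusted over the list alone. Among the male germ cell rises, Dnmt3a was at 2.15 on its brightest probe but at -0.31 and -0.46 on its other probes. The Dnmt3a call was lost with the mean of its probes (limma adjusted p = 0.0608). Retinoic acid genes gave 8, 3 and 13 of 24, with 11 and 3 when adjusted over the list alone (median 0.32, 0.0341, lost with the mean of probes at 0.0583, without the first E12.5 array at 0.0611 and without the second E13.5 array at 0.0658). Falls led among erythroid genes (6 of 15, 0 rises, 9 not past, 7 falls and 0 rises when adjusted over the list alone, median -1.09, 0.00385) and mesonephros and duct genes (5 of 17, 2 rises, 10 not past, 7 falls and 2 rises when adjusted over the list alone, median -0.65, 0.00385). They also led among cell cycle genes (7 of 31, 0 rises, 24 not past, the same when adjusted over the list alone, median -0.21, 0.0129, lost without the second E13.5 array at 0.0658). In the hypoxia list 5 of 17 fell, 0 rose and 12 did not pass, with 4 and 0 when adjusted over the list alone (median -0.32, 0.00765). In the endothelial list 8 of 21 fell, 1 rose (Eng) and 12 did not pass, with 9 and 1 when adjusted over the list alone (median -0.18, 0.0341). The endothelial call was lost with no filter (0.0838), with unnamed probes (0.0506) and without the first E12.5 array (0.0564) or the first E13.5 array (0.063), and its median was -0.30 without the second E12.5 array. These 10 lists had an adjusted p = 0.457 to 0.551 with an estimated correlation. The other 12 lists did not pass (camera adjusted p 0.0631 to 0.885), and the pluripotency list, at 0.147 with 1 rise and 5 falls of 21, passed without the first E13.5 array (0.0481) and with normexp (0.0429). Pregranulosa genes passed with the filter on all 6 arrays (0.0393), and oogenesis genes with normexp (0.0369) and median scaling (0.0353).

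**Figure D2:**
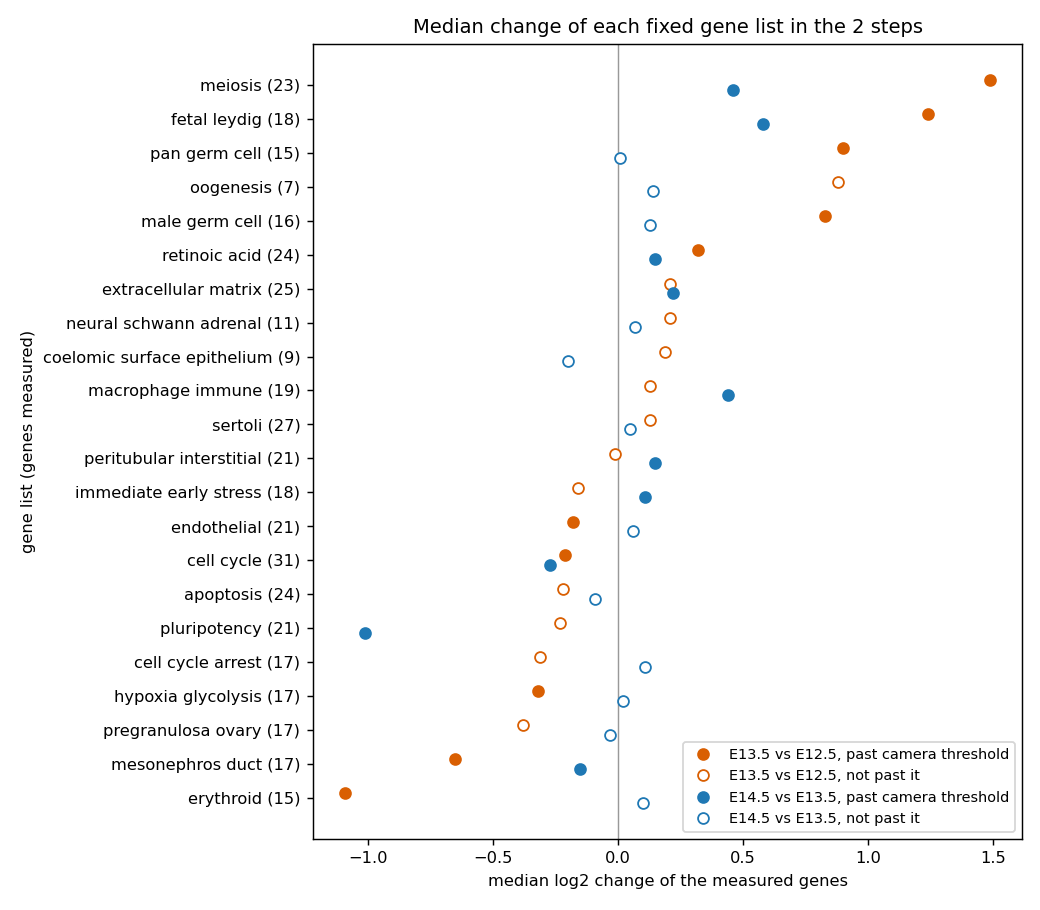
Median log2 change of the measured genes of 22 lists from E12.5 to E13.5 and from E13.5 to E14.5, filled where camera at the preset correlation passed. Meiosis had medians of 1.49 and 0.46 and pluripotency of -0.23 and -1.01, the -0.23 running from -0.47 without the first E13.5 array to 0.003 without the second E12.5 array. No list passed with an estimated correlation.

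Over all genes, 4318 of 13484 changed between E12.5 and E13.5, 2432 higher and 1886 lower, and 1163 by at least 2-fold. Hao2 (24.6-fold), Taf7l (22.9-fold), Jak3 (17.5-fold on its brightest probe, with 1 of its 3 probes at -0.48), Lypd4 (at least 31.5-fold), Capn9 (at least 4.82-fold) and Dhrs7c (at least 5.05-fold, and 3.29-fold without the second E13.5 array) rose. Khdc1c fell by 4.09 ± 0.45, and was at -4.80 and -3.38 without the first or second E13.5 array. Sprr2d (at least 7.97-fold), Avpr1b (at least 6.90-fold), Kcnc1 (at least 6.13-fold, and 3.28-fold without the second E12.5 array) and Mmp16 (at least 4.13-fold) fell. Kcnc1 was read on its brightest probe, and its other probes, well above background on 0 arrays, were at -0.74 and -0.84. The count fell with single arrays left out, to 2142 and 2648 without the first or second E12.5 array and to 2014 and 1395 without the first or second E13.5 array. It was 2865 with no background filter. With median scaling 1739 genes were higher and 1741 lower, and with normexp 3300 and 1978, so the excess of rises depended on the processing.

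Between E13.5 and E14.5, within 1 slide, pluripotency genes were lower and fetal Leydig genes higher as lists in camera at the preset correlation, while few single genes passed. With an estimated correlation both lists had an adjusted p = 0.481, and fry passed 0 of 22 lists. All 21 pluripotency genes had a negative change, such as Tfap2c (-2.22 ± 0.28, adjusted p = 0.0877) and Prdm1 (-1.09 ± 0.21, adjusted p = 0.102). All 18 fetal Leydig genes had a positive change, such as Cyp11a1 (1.51 ± 0.24, adjusted p = 0.0924) and Star (0.91 ± 0.20, adjusted p = 0.114). Among meiosis genes Dmc1 was at 1.16 ± 0.17 (0.0924), Sycp3 at 1.04 ± 0.22 (0.105), Stra8 at 0.50 ± 0.17 (0.219) and Rec8 at 0.42 ± 0.20 (0.324). The changes of Ddx4 (0.03 ± 0.11), Dazl (-0.09 ± 0.19), Nanos2 (0.18 ± 0.40), Dnmt3l (0.86 ± 0.32), Pou5f1 (-0.12 ± 0.37), Sox9 (-0.25 ± 0.20) and Amh (-0.40 ± 0.12) did not pass either.

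By list, 0 members passed limma over all genes in any of the 22 lists between E13.5 and E14.5, so the following are list results. Of 21 pluripotency genes 0 rose and 9 fell when adjusted over the list alone (median -1.01, camera adjusted p = 1.31e-09), and the median was -0.62 without the second E14.5 array. Of 18 fetal Leydig genes 15 rose and 0 fell when adjusted over the list alone (median 0.58, 1.31e-09). Of 23 meiosis genes 4 rose and 1 fell when adjusted over the list alone (19 positive and 4 negative, median 0.46, 0.000167, median 0.28 without the first E13.5 array). Cell cycle genes gave 0 and 0 when adjusted over the list alone, with 29 of 31 negative (median -0.27, 2.5e-06), and macrophage genes 7 and 0 of 19 (17 positive, median 0.44, 3.35e-05). Retinoic acid genes gave 2 and 0 of 24 (median 0.15, 0.0135, and 0.0674 without the first E14.5 array). Extracellular matrix genes gave 0 and 0 of 25 (median 0.22, 0.00181, lost without the first E13.5 array at 0.0649 and the second E14.5 array at 0.216). Their median ran from 0.10 to 0.39 with single arrays left out. Immediate early and stress genes gave 0 and 0 of 18 (median 0.11, 0.0469), peritubular genes 2 and 1 of 21 (median 0.15, 0.0469), and mesonephros and duct genes 0 and 5 of 17 (median -0.15, 0.0427). These 3 calls were lost without several single arrays and in other settings. The stress list was at 0.0602 without either E12.5 array, 0.0626 and 0.107 without the first or second E13.5 array and 0.129 without the first E14.5 array, with a median of 0.23 without the second. It was also lost with normexp (0.0671), quantile normalization (0.0711), no filter (0.0922), the replicate block (0.0502) and 4 arrays only (0.0602). The peritubular list was at 0.256 without the first E13.5 array at 0.087 and 0.0581 without the first or second E14.5 array, and at 0.0922 with no filter. The mesonephros list was at 0.0621 without either E12.5 array, 0.0648 without the second E13.5 array and 0.346 without the second E14.5 array, with medians from -0.41 to -0.06, and was lost with median scaling (0.0669), the mean of probes (0.073) and 4 arrays only (0.0621). These 10 lists had an adjusted p = 0.481 to 0.566 with an estimated correlation, and fry passed 0 of the 22 (smallest adjusted p = 0.139). The other 12 lists did not pass (camera adjusted p 0.141 to 0.921), though oogenesis passed with normexp (0.0407) and neural genes with the filter on all 6 arrays (0.0325).

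Over all genes, 7 of 13484 changed between E13.5 and E14.5 in limma (adjusted p = 0.0464 for each), with 2489 at an unadjusted p under 0.05. Prss45 rose 3.44-fold (1.78 ± 0.13), Arsj 3.34-fold (1.74 ± 0.15) and P2ry14 2.51-fold (1.33 ± 0.11). Spag16 rose at least 3.24-fold, Pi15 at least 2.26-fold and Rtl3 at least 1.73-fold. With normexp 4 of these were lost, Prss45 at 0.45 (adjusted p = 0.143), P2ry14 at 0.50 (0.0616), Pi15 at 0.35 (0.197) and Rtl3 at 0.52 (0.0811). Of the 7 calls 7 held with median scaling, 2 with normexp, 2 with quantile scaling and 0 with the replicate block, the mean of probes or 4 arrays only. Ldoc1 fell, with no fold since it was well above background on 0 E14.5 arrays and 1 E13.5 array, and it was chosen after its values were seen. The count was 0 without either E12.5 array or the first E13.5 array, 42 without the second E13.5 array, 42 without the first E14.5 array and 1 without the second. With median scaling it was 95, 76.8% of them higher against 85.7%, and with quantile scaling it was 5, 60% of them higher. Median scaling put the median change of all genes at -0.11 in place of -0.01.

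In a test of the difference between the 2 steps, 66 genes had a second step that differed from their first, 30 upward and 36 downward. Camera was run on this difference as well, a test chosen after the data were seen. Meiosis genes had a median of -1.01 for the second step minus the first (camera adjusted p = 0.000127, adjusted p = 0.628 with an estimated correlation), with 0 of 23 members past and 0 and 7 when adjusted over the list alone. Fetal Leydig genes were at -0.66 (0.00161, adjusted p = 0.628 with an estimated correlation), with 2 of 18 members past and 1 and 6 when adjusted over the list alone. At the preset correlation camera also passed the male and general germ cell lists (downward) and the arrest, hypoxia, endothelial, macrophage and erythroid lists (upward), with an adjusted p = 0.628 to 0.649 with an estimated correlation. The pluripotency list did not pass this test (median -0.84, camera adjusted p = 0.0671). The count of 66 was 0 without the first E12.5 array, 1 without the second, 11 and 2 without the first or second E13.5 array, and 1 without the second E14.5 array. The first step spans the 2 slides, so this difference cannot be told apart from a slide difference. A test of any stage difference called 5480 genes, and 2851 and 3051 without the first or second E12.5 array.

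**Figure D3:**
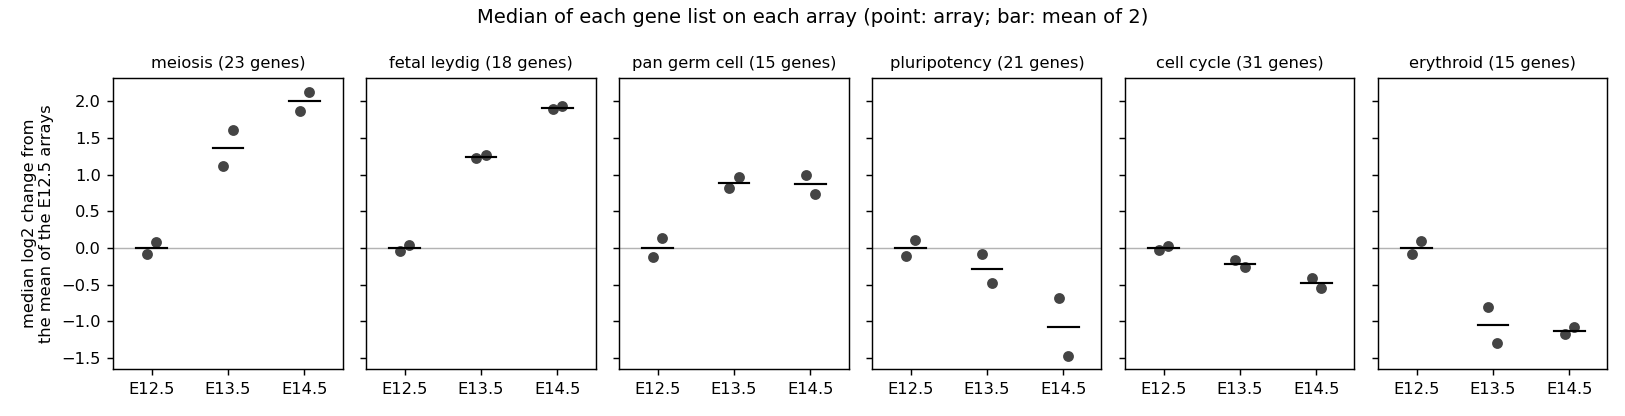
Median log2 change from the mean of the E12.5 arrays for 6 gene lists, with points for arrays and bars for the mean of 2. Pluripotency was at -0.68 and -1.47 on the 2 E14.5 arrays, while meiosis was at 1.87 and 2.13.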

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

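The use of spot medians in normexp, the inclusion of probes without a symbol and the tests with a trend and an ordinary prior were chosen only after the data were seen, and the other alternatives before. Of 284 results on named genes, 273 kept their direction and side of the threshold with median scaling, 274 with quantile scaling, 234 with normexp and 240 to 273 with single arrays left out. In the deposited values, which allow no test, 39 of the 284 differed from the reported change by more than the SD between replicates, and 0 called ones reversed. The count of genes changed between E12.5 and E13.5 (4318) was 2865 with no background filter, 1163 with a 2-fold minimum and 1395 to 3971 with single arrays left out. Between E13.5 and E14.5 (7 genes) it was 400 with normexp, 95 with median scaling, 333 with a trend and robust prior, 336 with a trend alone, 1 with the replicate block, 1 with unnamed probes and 0 to 42 with single arrays left out. It was 0 with limma with no filter, with the filter on all 6 arrays, with the mean of probes and with 4 arrays only, beside 2489 genes at an unadjusted p under 0.05 in the reported fit. Between E12.5 and E14.5 (6299) it was 1924 with a 2-fold minimum and 3937 to 5449 with single arrays left out. The test of any stage gave 2851 to 4571 with single arrays left out. Genes whose steps differed (66) numbered 481 with normexp, 42 with quantile scaling, 173 with median scaling, 262 with the filter on all 6 arrays, 25 with the mean of probes, 552 and 495 with a trend and a robust or ordinary prior, 5 with the replicate block and 6 with unnamed probes. They numbered 0 with no filter in limma and 0 to 63 with single arrays left out. Lists past the threshold (10, 10 and 12) were 0, 0 and 0 with an estimated correlation, and by fry 9, 0 and 14. Fry passed partly other lists (fry adjusted p in brackets). Between E12.5 and E13.5 it did not pass cell cycle (0.0727), hypoxia (0.118) or mesonephros genes (0.0644), but passed Sertoli (0.022) and oogenesis genes (0.022). Between E12.5 and E14.5 it did not pass pluripotency (0.0619), hypoxia (0.0921) or pregranulosa genes (0.0523). There it passed Sertoli (0.0133), oogenesis (0.0194), peritubular (0.025), endothelial (0.0246) and apoptosis genes (0.0457). Pfkp reversed with the mean of its probes, to 0.049 at E13.5 and 0.129 at E14.5 against E12.5. Except where the construction shows it (fewer arrays, a fold minimum), the cause was not tested. Of the genes called from E12.5 to E14.5, 5206 were also called with median scaling, 5962 with quantile scaling and 5555 with normexp. Deviations of the first arrays correlated across genes at -0.043, -0.06 and 0.229 between stages, so the replicate numbers were not read as pairs. A lone array was assumed to vary like the others. A random slide block was not run, since each stage lies on 1 slide. Signal over background limits the dim genes, which have bounds only.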

Other observations

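The splits of the slide test into rises, falls and large changes, the germ cell and blood tests, the intervals used for the spike-in and blood tests, the other sets of spike-in probes and genes, and the ranking in the deposited table were chosen only after the results were seen. In the authors' deposited table, among named probes well above background on all 6 arrays, Stra8 had the highest ratio at E13.5 (35.1) and at E14.5 (45.8), against 5.97 at E12.5. Cyp26a1, the related enzyme that breaks down retinoic acid, had deposited ratios of 11.6, 13.5 and 20.6 at the 3 stages, and M1ap, a meiosis gene, had 0.89, 10.2 and 23.3. At E12.5 the lowest deposited ratio was that of Cyp11a1 (0.018) and the highest that of Kctd14 (17.4). The reference of these ratios is not stated, so they are not read as changes against any genotype.

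Counts of 4318 and 6299 genes differed from E12.5, and E12.5 alone lay on the first slide. If the slide alone were the cause, called genes should go on equally in either direction within the second slide, yet 67.2% and 76.8% went on in the same direction when the 2 steps shared no E13.5 array. For rises the shares were 73.7% and 83.2%, which argues against the slide alone, but for falls they were 57.7% and 67.2%, so a slide effect cannot be told apart for the falls. Of falls by at least 4-fold only 43.6% and 60.9% went on (55 and 92 genes), against 72.7% and 84.8% of such rises. The 7 spike-in probes well above background scattered between the slides 0.2 times as much as genes (95% interval 0.13 to 0.45). That share argues against hybridisation or scanning as the sole source for bright probes. The spike-in SD was 0.151 between slides and 0.034 from E13.5 to E14.5 within the second slide, against 0.745 and 0.397 for genes. A difference between the slides, smaller than that of genes, was therefore present in the spike-in probes too. The interval reached 0.51 against the 12534 genes well above background on all arrays, so a part of the scatter is not excluded. The 3 dim spike-in probes left out were all lower on the second slide (-0.50, -0.44 and -0.37), and with all 10 the share was 0.31 (interval 0.21 to 0.56). Hybridisation or scanning therefore stays open for dim genes. RNA preparation and the stage itself stay open, and both may contribute.

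Pluripotency genes were lower on the second E14.5 array than on the first, by a median of -0.70 with 21 of 21 lower. Other list medians, as changes from E12.5, moved both ways between these arrays. Mesonephros genes were at -0.45 and -0.96 on the first and second array, and hypoxia genes at -0.02 and -0.56. Matrix genes were at 0.29 and 0.63, and meiosis genes at 1.87 and 2.13. Fewer germ cells in the sample of the second array could lower the pluripotency genes. The general germ cell list without pluripotency genes differed by only -0.05, with 9 of 14 lower, which argues against fewer germ cells. Its interval of -0.22 to 0.12 came from resampling genes and does not cover the spread between samples. Embryos further on in development could also lower the pluripotency genes. Across genes the array difference correlated at 0.116 with the change from E12.5 to E13.5, between the bounds of 0.1 and 0.2 set in advance. That explanation cannot be told apart on these arrays, since genes are not independent replicates and each stage has 2 arrays. The change from E12.5 to E13.5 also spans the 2 slides. Any slide difference in that change is not development, so the correlation is no clean measure of it. Against E13.5 the pluripotency list was lower on both E14.5 arrays, at -0.62 and -1.33.

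Erythroid genes were lower after E12.5, the embryonic globins by a median of -2.86 (3 genes) and the other 12 by -0.73 (interval -1.33 to 0.19). The intervals given for these genes come from resampling genes, not samples. Less blood in the later samples could lower both groups alike, while a switch from embryonic globins would lower mainly the first. The ratio of the medians was 0.26 with an interval of -0.07 to 0.55, which includes the bound set for the test, so less blood cannot be told apart. Within the second slide, from E13.5 to E14.5, the erythroid list had a median change of 0.10, with 9 of 15 positive. Hbb-bh1 was lower in that step, at -1.59 on its brightest probe and -1.84 on its other probe, but 0 of the 15 genes passed in limma. The slide difference stays open for the list, since the falls were the part the slide test did not settle.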
